A study of Drosophila melanogaster with 8 samples.

How the data were processed

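Total RNA was measured by sequencing in wing imaginal discs, the larval epithelia that give rise to the adult wing and thorax, of Drosophila melanogaster. Per the labels, larvae in the third instar were raised at 25 °C and dissected on day 7 after the eggs were laid, with 150 discs and 2 µg of RNA per library and a stranded total RNA kit with rRNA removal. The labels disagree on the sequencing: one names single-end reads and another paired-end reads of 100 bp, on different models of sequencer, so the layout is left open here. The 8 libraries fell into 2 groups of 4 biological replicates, named by their titles. Control discs carried nub-Gal4, a driver active in the wing pouch and hinge, and a red fluorescent protein. The second group also carried an RNAi construct against ecd. Because the labels call the 4 libraries of a group biological replicates, the p-values measure the spread between such replicates.

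The authors deposited a table of normalized counts, a signal per gene or insertion that is never negative and not whole, with a column for each library. Per the submitters' processing notes, reads were handled with FastQC, cutadapt 3.5, kallisto 0.46.1 and DESeq2 1.34.0 on BDGP6; their settings, the transcript set and the use of strand are not given in the sources used here. The authors' deposited table of their own comparison gives the mean normalized count, a log2 fold change with its standard error, a score (the Wald statistic), and p-values with adjusted p-values, per the file headers. The row means of the normalized counts equal the authors' deposited mean to a relative difference of 4.78e-09.

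The tables held 23932 rows, of which 18354 were genes and 5578 were single transposable element insertions; 6310 rows were at 0 in all 8 libraries. Gene symbols came from a table of gene names that matched 23366 row identifiers and left 566 without a symbol. Coordinates and intron numbers were taken from the Ensembl annotation of BDGP6, the assembly that the submitters' notes name, and are 1-based. In 1516 gene rows the 8 values equalled those of another gene row to 4 decimals, as happens where annotated transcripts are identical, so values of near-identical copies and of overlapping genes are uncertain. Without a stated strand setting, genes with an antisense partner are uncertain too.

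Low values lay near steps of about 1 read, but the step differed from gene to gene within a library. With the most frequent step of each library, between 70.9% and 86.8% of values up to 20 reads came within 0.1 of a whole number, too few to recover whole reads, and no count model was run. The most frequent step was worth 1.04 to 1.20 normalized counts in control libraries and 0.831 to 0.980 in libraries labelled ecd-RNAi. These steps put the depth at 29500000 to 36500000 reads in control libraries and 31100000 to 37600000 reads in libraries labelled ecd-RNAi, as an approximation. A count of 0 allows up to 3 reads, on average 3.42 normalized counts in a control library and 2.64 in a library labelled ecd-RNAi. Where the mean of a group lay under that floor, folds are given as lower bounds against it (at least N-fold), which covers counting error only.

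The comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend, two-sided) on log2(normalized count + 1), with a pseudocount of 1, for gene rows with a mean of at least 10 normalized counts over the 8 libraries. All 8 libraries entered the fit with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes from this fit are differences of mean log2(value + 1); folds given as N-fold are ratios of group means, and the 2 can differ in either direction for low genes and for genes with 1 outlying library. Means carry the standard deviation over 4 libraries.

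A set of 31 gene lists was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, beside camera with an estimated correlation and fry. All 16 calls made at the preset correlation were lost with the estimated correlation. The estimate was 0.014 for the glutathione list, 0.015 for the autophagy list and -0.025 for the apoptosis list, close to the preset or below it. In these lists a higher correlation among members does not account for the loss. In the other called lists the estimate lay between 0.058 (Xrp1 list) and 0.59 (cytosolic ribosomal proteins). The lists were the core spliceosome, Xrp1 and integrated stress response, glutathione S-transferases, antioxidant control, JNK signalling, JAK/STAT signalling, apoptosis, DNA damage response, cytosolic heat shock proteins, endoplasmic reticulum unfolded protein response, proteasome, autophagy, ribosome biogenesis, aminoacyl-tRNA synthetases, cytosolic ribosomal proteins, mitochondrial respiratory chain, cell cycle, wing pouch, notum and hinge, ecdysone response, cuticle proteins, glycolysis, serine and one-carbon metabolism, nonsense-mediated decay and innate immune effectors, and markers of hemocytes, fat body, trachea, adult muscle precursors, neurons and salivary gland. Of the list entries, 10 were not found and are not analysed here. The Xrp1 list was drawn up knowing the title of the series, so it is not independent evidence of its direction.

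The named genes followed a rule fixed before the data were examined, as were the lists, the design and the first set of other settings. The rule took ecd, Xrp1, the 6 genes with the largest rise and the 6 with the largest fall among called genes whose groups did not overlap and whose mean was at least 50 in the higher group, and from each list the called member or 2 members with the largest absolute log2 fold change. It gave 62 genes. Genes outside the rule are said to be chosen after their values were seen.

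The scripts were tested on simulated data for this comparison with 9380 genes and a dispersion of 0.02. The test recovered 49.1% of 53 genes changed 1.5-fold, 97.4% of 77 changed 2-fold and 100% of 70 changed 4-fold, with 5% of calls false. It called a shifted list at a false discovery rate of 3.48e-24 and 0 of 30 random lists. The simulated genes varied independently and few of them changed, whereas 62.5% of genes passed in the data. These rates check the scripts and do not give the error rates of the calls made here. Other settings fixed in advance were other pseudocounts, no filter or a stricter one, quantile normalization, recentring on the median, the replicate number as a block, library weights, a fold threshold, the authors' deposited table, an estimated correlation, and leaving out each library in turn. Added after seeing the data were fits that included insertions, took protein-coding genes alone, or left out both control replicate 2 and ecd-RNAi replicate 1, and a limma fit of transposable element families as sums of at least 2 insertions. Insertions were otherwise kept out of the gene test because their reads can be shared between copies.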

Results

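The series, whose title names the transcription factor Xrp1 and spliceosome dysfunction, compared wing discs with and without RNAi against ecd. The gene ecd (ecdysoneless) encodes a conserved protein required for pre-mRNA splicing and for making the steroid hormone ecdysone. RNAi was driven with nub-Gal4, so the notum and part of the hinge of each disc lay outside its domain. There were 4 control libraries and 4 libraries labelled ecd-RNAi.

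Normalized counts summed to 37880000, 37731000, 35111000 and 35559000 in control replicates 1 to 4, and to 32624000, 30509000, 29086000 and 27404000 in ecd-RNAi replicates 1 to 4. Ribosomal RNA made up 51.0% ± 2.07 of the control signal and 29.4% ± 3.91 of that in libraries labelled ecd-RNAi (SD, n = 4). Protein-coding genes made up 43.5% ± 1.82 and 52.1% ± 2.99. Other non-coding RNA rose from 3.73% ± 0.294 to 8.60% ± 0.486, and transposable element insertions from 0.379% ± 0.0476 to 7.82% ± 1.69, with no overlap between the groups in either share.

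**Figure D1:**
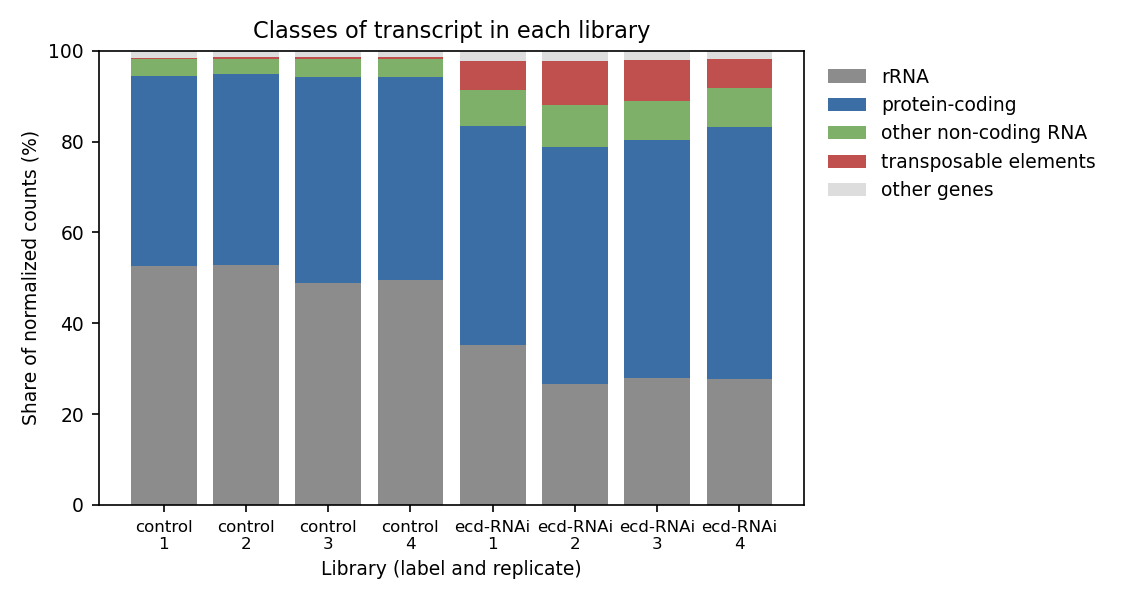
Share of normalized counts (y axis, percent) by class of transcript in each of the 8 libraries (x axis, group label and replicate). Ribosomal RNA lay between 48.9% and 52.9% in the control libraries and between 26.6% and 35.2% in the libraries labelled ecd-RNAi, and transposable elements between 0.327% and 0.441% and between 6.36% and 9.64%.

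The transcript of ecd itself (FBgn0000543, chromosome 3L, 2263581 to 2265857, minus strand) was measured first as a check of the labels. It was 1052, 1015, 1047 and 998 normalized counts in control replicates 1 to 4 and 1416, 1208, 1307 and 1462 in ecd-RNAi replicates 1 to 4. The targeted gene was thus higher, not lower, in every library labelled ecd-RNAi, 1348 ± 114 against 1028 ± 25.9 (SD, n = 4), a log2 fold change of 0.39 (SE 0.06, limma with Benjamini-Hochberg adjusted p = 0.000245). It goes against the label, and every direction given here is that of the libraries labelled ecd-RNAi relative to control. The exons of ecd overlap those of another gene on the opposite strand, CG13807, and the values are per gene, so RNAi hairpin reads are not separated from the endogenous transcript.

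Xrp1 (FBgn0261113, chromosome 3R, 18914968 to 18926989), a bZIP transcription factor of stress responses and cell competition, rose 3.09-fold, from 4367 ± 634 to 13480 ± 320 normalized counts (SD, n = 4; log2 fold change 1.64, SE 0.08, limma with Benjamini-Hochberg adjusted p = 1.08e-07). Of the 22 measured members of the Xrp1 and integrated stress response list, 16 rose, 5 fell and 1 did not pass, and the counts adjusted over the list alone were also 16 and 5. Ilp8, a relaxin-like peptide that delays the larval to pupal transition when tissue is damaged, rose 180.0-fold from 35.8 ± 30.8 to 6448 ± 1682. GstE6, a glutathione S-transferase, rose 81.7-fold from 33.0 ± 32.0 to 2694 ± 106. Control replicate 2 held the highest value of both genes among controls, and without it the folds were 301.4 and 158.5. The list was higher as a set (median log2 fold change 0.77, limma camera with Benjamini-Hochberg adjusted p = 0.00405; adjusted p = 0.428 with an estimated correlation), and because it was drawn up knowing the title of the series it is not independent evidence of its direction.

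**Figure D2:**
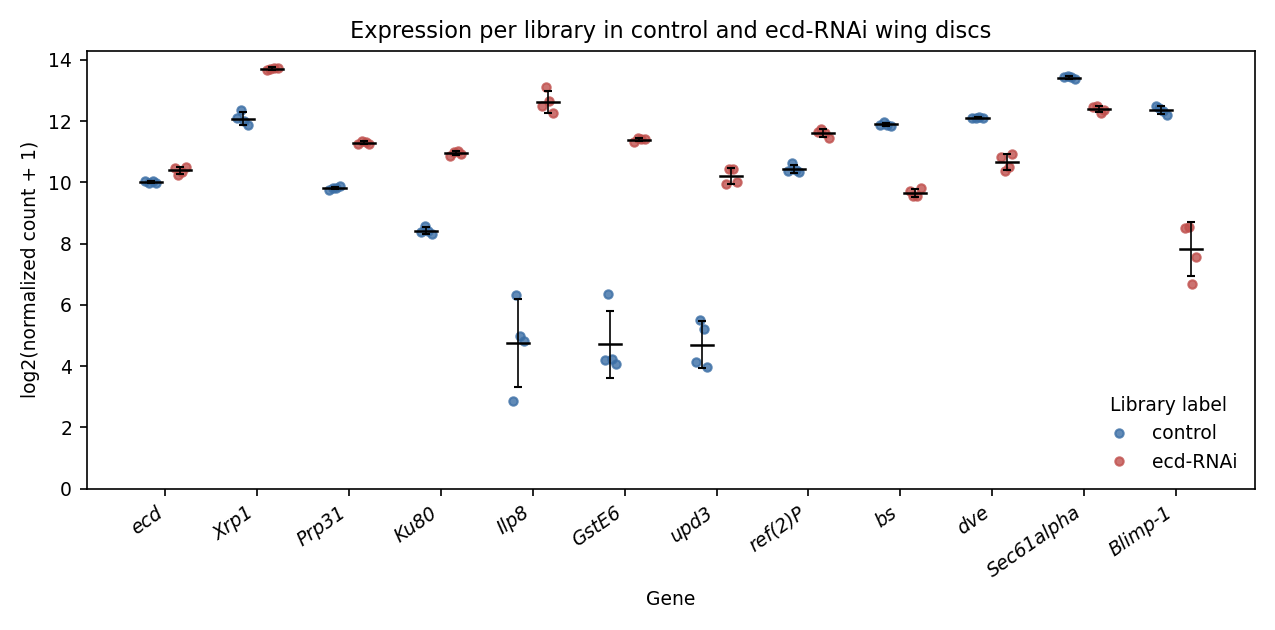
Expression of 12 named genes (x axis) as log2(normalized count + 1) (y axis) in each library, with points for single libraries, horizontal bars for group means and error bars for the SD over 4 libraries. The 4 libraries labelled ecd-RNAi lie above the 4 controls for ecd (1208 to 1462 against 998 to 1052 normalized counts), and for Xrp1, Prp31, Ku80, Ilp8, GstE6, upd3 and ref(2)P, and below them for bs, dve, Sec61alpha and Blimp-1.

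Among glutathione S-transferases and glutathione synthesis enzymes, 20 of 32 rose and 6 fell, the same numbers when adjusted over the list alone (median log2 fold change 0.85, camera with Benjamini-Hochberg adjusted p = 0.000471; adjusted p = 0.326 with an estimated correlation). GstD5 rose at least 38.4-fold, from 2.54 ± 2.61 to 131 ± 41.1 normalized counts. In the JNK list, which covers a stress kinase pathway and its targets, 21 of 28 rose and 4 fell, also when adjusted over the list alone (median 0.81, camera adjusted p = 0.000225; adjusted p = 0.451 with an estimated correlation). The JAK/STAT list had 9 of 14 higher and 2 lower by both adjustments, over all genes and adjusted over the list alone (median 0.55, camera adjusted p = 0.0196; adjusted p = 0.529 with an estimated correlation). The ligand genes upd3 and upd2 had its largest folds: upd3 rose 42.8-fold from 27.8 ± 14.6 to 1192 ± 215 and upd2 16.7-fold from 49.6 ± 45.5 to 827 ± 197. These lists share entries and are not independent. The JNK and JAK/STAT lists share upd1, upd2, upd3 and chinmo. The Xrp1 list shares Ilp8, Atf3 and Gadd45 with the JNK list and GstE6 with the glutathione list.

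Genes of DNA damage, cell death and autophagy were also mostly higher. In the DNA damage response and repair list 30 of 43 rose and 9 fell, also when adjusted over the list alone (median 0.40, camera adjusted p = 6.25e-05; adjusted p = 0.451 with an estimated correlation). Ku80, which binds broken DNA ends, rose 5.80-fold from 343 ± 27.4 to 1989 ± 101. Corp, a p53 regulator, was at 0 in all controls and at 94.6 ± 29.4 in libraries labelled ecd-RNAi, at least 27.7-fold higher. The apoptosis list is not independent of these: it shares Corp and p53 with the DNA damage list, and rpr, hid and egr with the JNK list. In the apoptosis list 10 of 17 rose and 4 fell, the same when adjusted over the list alone (median 0.22, camera adjusted p = 0.0489; adjusted p = 0.428 with an estimated correlation). Damm, a caspase, rose 5.72-fold to 20.2 ± 2.21. Only 2 apoptosis genes fell without control replicate 1 or 3 or ecd-RNAi replicate 2. The apoptosis call was lost in 10 other settings as well, 5 of them fits without 1 library (adjusted p between 0.0501 and 0.0615 without control replicate 1, 2 or 3 or ecd-RNAi replicate 1 or 3). In the autophagy list 15 of 24 rose and 3 fell, also when adjusted over the list alone (median 0.23, camera adjusted p = 0.00529; adjusted p = 0.384 with an estimated correlation). The autophagy gene Atg18b rose 2.35-fold to 611 ± 66.5, and ref(2)P, the p62 cargo receptor, 2.26-fold to 3141 ± 278. Of innate immune effectors 7 of 11 rose and 0 fell, by both adjustments, that over all genes and adjusted over the list alone (median 0.73, camera adjusted p = 0.0096; adjusted p = 0.451 with an estimated correlation). This list had 31 entries, and those not tested lay below the filter on low values. Without that filter 8 of 25 rose and 0 fell. It mixes antimicrobial peptide genes with regulators and receptors, and the 2 members named here are of the latter kind. Dif, an NF-kappaB factor, rose 19.3-fold to 2061 ± 115 (29.3-fold without control replicate 2) and PGRP-SA, a peptidoglycan receptor, 5.84-fold to 109 ± 26.7.

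In the endoplasmic reticulum unfolded protein response list 16 of 24 fell and 1 rose, also when adjusted over the list alone (median -0.27, camera adjusted p = 0.000221; adjusted p = 0.529 with an estimated correlation). Gp93, a chaperone of the endoplasmic reticulum, went from 11670 ± 286 to 5772 ± 682 normalized counts, and Sec61alpha, the core of the protein translocation channel, from 10990 ± 302 to 5398 ± 377, 2.02-fold and 2.04-fold lower. Of 33 proteasome genes 27 fell and 0 rose, also when adjusted over the list alone (median -0.32, camera adjusted p = 1.76e-05; adjusted p = 0.529 with an estimated correlation), and 17 fell with quantile normalization. The proteasome ATPase Rpt2 fell by 0.56 and the assembly factor Pomp by 0.60 on the log2 scale. Of cytosolic heat shock proteins 3 of 22 rose and 5 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.828). These counts hung on single libraries: 7 rose and 6 fell without ecd-RNAi replicate 4, 1 and 7 without ecd-RNAi replicate 2, and 1 and 5 without ecd-RNAi replicate 3. The small heat shock genes Hsp23 and Hsp67Ba were 2.15-fold and 2.13-fold lower, at 22140 ± 4501 and 1550 ± 318.

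Of 68 respiratory chain genes 53 fell, 1 rose and 14 did not pass, or 55 fell and 1 rose when adjusted over the list alone (median -0.30, camera adjusted p = 5.92e-08; adjusted p = 0.451 with an estimated correlation). Without control replicate 4 or ecd-RNAi replicate 4, 2 rose. The member that rose with all libraries was COX7AL, a cytochrome oxidase subunit gene near the floor in controls (1.15 ± 0.974), at 46.8 ± 7.67. Cytosolic ribosomal protein genes were slightly higher, with 53 of 82 rising and 6 falling, or 54 and 6 when adjusted over the list alone (median 0.18, camera adjusted p = 6.25e-05; adjusted p = 0.601 with an estimated correlation), and 35 rising and 9 falling after recentring on the median. RpS19b, a paralog at low level, fell from 17.5 ± 2.72 to 7.03 ± 1.66. The rRNA share, 51.0% in control and 29.4% in libraries labelled ecd-RNAi, also depends on how much rRNA the kit removed from each library. Ribosome biogenesis genes went both ways (8 of 32 rose and 11 fell, 9 and 12 when adjusted over the list alone, 5 and 14 after recentring on the median, camera adjusted p = 0.828): Non1, a nucleolar GTPase, rose 2.71-fold and Nop56, a snoRNP core protein, fell by 0.64 on the log2 scale. Of aminoacyl-tRNA synthetases 7 of 20 rose and 7 fell, 8 and 7 when adjusted over the list alone (camera adjusted p = 0.839), with AlaRS 1.44-fold higher. The split hung on the scaling: 12 rose and 4 fell with quantile normalization, and 6 and 10 after recentring on the median.

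Genes of wing patterning and growth were mostly lower. All discs were dissected on day 7 and their stage was not otherwise measured here. For these lists and the ecdysone list, a difference in stage is therefore not told apart from an effect of the RNAi. In the wing pouch list 29 of 38 fell and 6 rose, also when adjusted over the list alone (median -0.41, camera adjusted p = 1.81e-05; adjusted p = 0.451 with an estimated correlation). The vein and intervein regulator bs (blistered) went from 3812 ± 125 to 807 ± 74.1 normalized counts, 4.72-fold lower, and the homeobox gene dve from 4411 ± 51.7 to 1642 ± 296, 2.69-fold lower. In the notum and hinge list 15 of 18 fell and 2 rose, also when adjusted over the list alone (median -0.49, camera adjusted p = 0.000703; adjusted p = 0.528 with an estimated correlation). Only 1 notum and hinge gene rose without control replicate 2, 3 or 4 or ecd-RNAi replicate 1, 2 or 3, and after either rescaling. The homeobox genes mirr and B-H1 fell by 0.99 and 0.96 on the log2 scale. In the cell cycle and DNA replication list 27 of 45 fell and 6 rose, also when adjusted over the list alone (median -0.17, camera adjusted p = 0.0143; adjusted p = 0.553 with an estimated correlation), and the call was lost with quantile normalization (adjusted p = 0.229). After recentring on the median 3 cell cycle genes rose. Cdk1 and CycB, which drive entry into mitosis, fell by 0.64 and 0.59 on the log2 scale.

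In the ecdysone response list 14 of 26 fell and 7 rose, also when adjusted over the list alone (median -0.51, camera adjusted p = 0.0489; adjusted p = 0.553 with an estimated correlation). Hr3, a nuclear receptor induced by the hormone, went from 1393 ± 533 to 45.2 ± 47.4 normalized counts, 30.8-fold lower and 60.9-fold without ecd-RNAi replicate 1, and the repressor Blimp-1 from 5281 ± 486 to 256 ± 134, 20.6-fold lower. The list's call did not hold in 9 other settings either, among them both rescalings (adjusted p = 0.126 and 0.142) and the fits without control replicate 2, 3 or 4 or ecd-RNAi replicate 4 (adjusted p between 0.05 and 0.0713). The glue gene Sgs7, a salivary gland marker that the hormone also controls, was at least 27.8-fold lower at 2.06 ± 1.38, and 3 of 4 salivary gland markers fell, also adjusted over the list alone (camera adjusted p = 0.169).

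Core spliceosome genes changed in both directions, with 14 of 47 rising and 22 falling, also when adjusted over the list alone (median -0.11, camera adjusted p = 0.476), and 8 rising after recentring on the median. Prp31, a component of the U4/U6 particle, rose 2.78-fold from 901 ± 28.9 to 2502 ± 87.8. The Sm protein gene SmD3, which overlaps an antisense RNA gene, went from 137 ± 52.6 to 24.1 ± 27.1, 5.67-fold lower and 10.5-fold without ecd-RNAi replicate 1; its adjusted p was 0.0131 in limma and 0.0809 in the authors' deposited table. Of nonsense-mediated decay factors 3 of 10 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.266), with the exon junction proteins mago and tsu falling by 0.84 and 0.56 on the log2 scale.

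Metabolic lists went both ways. Of antioxidant genes 9 of 22 rose and 8 fell, 9 and 9 when adjusted over the list alone (camera adjusted p = 0.401), with the malic enzyme gene Men 4.48-fold and the ferritin chain gene Fer2LCH 2.44-fold higher. Of glycolysis genes 9 of 18 rose and 4 fell, 9 and 5 when adjusted over the list alone, 6 and 6 after recentring on the median (camera adjusted p = 0.407): lactate dehydrogenase, Ldh, rose 3.82-fold to 1972 ± 359 (7.21-fold without control replicate 3), and fbp, an enzyme of gluconeogenesis, was 2.61-fold lower. Of serine and one-carbon genes 5 of 16 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.74), with the serine synthesis genes CG6287 and CG11899 3.79-fold and 2.08-fold lower. Only 3 serine and one-carbon genes rose without control replicate 1 or 2 or ecd-RNAi replicate 2 or 3. Of cuticle protein genes 8 of 23 rose and 6 fell, 9 and 6 when adjusted over the list alone (camera adjusted p = 0.174), and Cpr47Ec was at 0 in controls and at least 9.79-fold higher at 33.5 ± 2.27.

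No marker list of another cell type passed camera. With fry, which asks whether members move one way on balance and not whether they differ from other genes, 24 of all 31 lists passed. Among them, in the lower direction, were the tracheal, muscle precursor, neuronal and salivary gland lists (adjusted p = 0.000445, 0.000781, 0.000126 and 0.000285), although the median log2 fold change of the neuronal list was 0.01 and its mean -0.34. The hemocyte and fat body lists did not pass fry (adjusted p = 0.656 and 0.218). Of hemocyte markers 5 of 16 rose and 5 fell (camera adjusted p = 0.879), with the integrin gene ItgaPS4 4.49-fold higher at 49.6 ± 18.3. Without control replicate 2 or 3 or ecd-RNAi replicate 2 or 3 only 2 hemocyte markers fell, and 3 without control replicate 1. Of fat body markers 0 of 12 rose and 3 fell, or 0 and 2 when adjusted over the list alone, and 1 rose without control replicate 2 (camera adjusted p = 0.266), and the storage protein receptor gene Fbp1 was at 561 ± 284 in controls and 239 ± 193 in libraries labelled ecd-RNAi, 159 without replicate 4 (limma adjusted p = 0.0464, lost in 10 of the other settings). Of tracheal markers 2 of 12 rose and 7 fell (camera adjusted p = 0.125), with pio 2.06-fold lower. Of adult muscle precursor markers 3 of 19 rose and 9 fell (camera adjusted p = 0.123), with the myosin light chain Mlc2 4.85-fold higher. Of neuronal and sensory organ markers 2 of 14 rose and 5 fell (camera adjusted p = 0.503), with the sensory organ factor sens 7.10-fold lower at 23.8 ± 4.89. Only 3 neuronal markers fell without control replicate 3 or 4 or ecd-RNAi replicate 3. Only 1 rose without control replicate 2, 3 or 4 or ecd-RNAi replicate 2 or 4 or with quantile normalization, and 0 after recentring on the median. Adjusted over the list alone, the hemocyte, tracheal, muscle precursor and neuronal counts were the same.

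**Figure D3:**
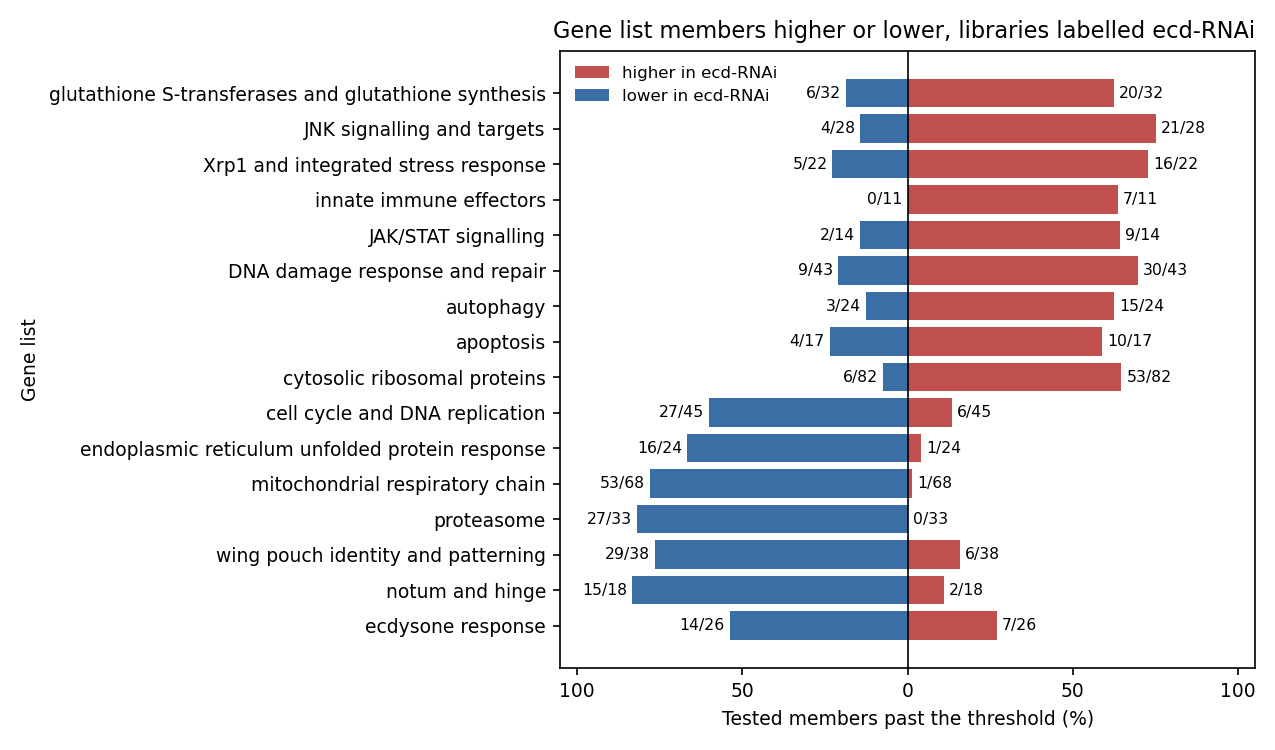
Share of tested members (x axis, percent) higher (right) or lower (left) in libraries labelled ecd-RNAi for the 16 gene lists past the camera test (y axis), with counts beside the bars. Of JNK genes 21 of 28 were higher, and of respiratory chain genes 53 of 68 were lower; after recentring on the median the 53 of 82 ribosomal protein genes became 35.

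Across all genes, 9380 were tested and 5859 (62.5%) passed limma with Benjamini-Hochberg adjustment, 2889 of them higher and 2970 lower. At least 2-fold, 816 were higher and 424 lower, against 683 and 553 with quantile normalization and 756 and 512 after recentring on the median. With each library recentred on its median, which moved the median log2 fold change to -0.09, the split was 2285 higher and 3691 lower, or 38.2% higher in place of 49.3%. The groups did not overlap for 5362 genes (57.2%, where chance gives 2.86%), and the first principal component, which parted the groups, held 75.4% of the variance.

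By difference of mean log2(normalized count + 1), which orders genes otherwise than the ratios of means given below, the 6 genes with the largest rise were CR10102, CG8620, orion, Tsf3, asRNA:CR45139 and CG44403. Of these, CR10102 (a pseudogene beside Arc1 on chromosome 2R), the chemokine-like orion, the transferrin Tsf3 and CG44403 were at 0 in all controls and at least 259-fold, 149.8-fold, 98.8-fold and 92.8-fold higher, at 886 ± 127, 512 ± 113, 338 ± 25.8 and 317 ± 35.1 normalized counts. CG8620 rose from 4.68 ± 6.50 to 1926 ± 182 (411.5-fold, and at least 574-fold without control replicate 2), and asRNA:CR45139 from 13.2 ± 26.5 to 896 ± 143 (67.7-fold, and at least 254-fold without control replicate 1, the control library that held it). By the same measure the 6 with the largest fall were snoRNA:Psi28S-1837a, CR43482, aos, fok, Pbp45 and CG46321. The snoRNA, the EGFR antagonist gene aos, fok and Pbp45, a subunit of the complex that activates snRNA genes, were at 0 in all libraries labelled ecd-RNAi, at least 164-fold, 126-fold, 90.5-fold and 35.3-fold lower than the 435 ± 64.0, 333 ± 80.2, 239 ± 73.5 and 93.2 ± 7.46 in controls. CR43482 went from 838 ± 212 to 5.76 ± 11.5, with a signal in ecd-RNAi replicate 4 alone and at least 313-fold lower without it. CG46321 went from 423 ± 207 to 9.56 ± 14.7 (44.2-fold lower, and at least 159-fold without ecd-RNAi replicate 1), but shares exons with Hr3, so that reads of the pair are not told apart.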

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

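The tests of control replicate 2 and of the transposable element families were chosen only after the results were seen. A library was singled out where its gap to the nearest of the other 3 of its group, divided by the range of the group, was above Dixon's 95% critical value for 4 libraries. Over 67 measures, 62 genes and 5 depth measures, this held for 10 of 134 groups of 4 libraries, where chance gives about 1 in 20, or 6.7.

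In control replicate 2, GstE6 was at 81.0 normalized counts against 15.8 to 17.8 in the other controls, and CG8620 at 14.3 against 0 to 2.37. Ldh was at 1243 in control replicate 3 against 216 to 322, and asRNA:CR45139 at 52.9 in control replicate 1 against 0. Among libraries labelled ecd-RNAi, CG46321 was at 31.5 in replicate 1 against 0.546 to 4.51, and CR43482 at 23.0 in replicate 4 against 0. Nop56 was at 2699 in replicate 4 against 2477 to 2512, AlaRS at 10790 in replicate 2 against 9669 to 9819, and Sgs7 at 0 in replicate 3 against 2.61 to 2.98. The rRNA share was 35.2% in ecd-RNAi replicate 1 against 26.6% to 27.9%.

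Control replicate 2 also held the highest control level of Arc1 (3252 normalized counts, against a control mean of 971 without it) and of copia. A small carry-over of a library labelled ecd-RNAi was one candidate explanation, and would add to every transcript 1 share of its level there. The excess was 0.612% of the ecd-RNAi mean for Arc1 and 1.48% for copia (SD from the other 3 controls 0.0743 and 0.172), and with any library labelled ecd-RNAi as the source the 2 shares lay at least 0.377 percentage points further apart than 2 SD, which argues against carry-over as the whole cause. Over 21 genes at 0 in the other controls the Arc1 share predicts about 22.2 reads (95% Poisson interval 13 to 32, which covers counting error only), and about 4 were seen, all of 1 gene, but these reads are approximate and near the floor. A difference between the discs of this library and the other controls stays open and was not tested.

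Transposable element insertions lay outside the gene comparison and gave a large signal. The LTR retrotransposon copia, summed over its 39 annotated insertions, averaged 1834000 ± 432600 normalized counts in libraries labelled ecd-RNAi (SD, n = 4), against 14900 to 43610 in the controls, and made up 77.1% to 79.5% of all insertion signal there. Of 106 families, 44 rose and 19 fell (limma with Benjamini-Hochberg adjustment), and 43 rose and 18 fell without control replicate 2. The LTR elements flea, invader4 and springer rose 36.2-fold, 55.4-fold (99.7-fold without control replicate 2) and 25.4-fold (log2 fold changes 5.19, 6.11 and 4.81), while gypsy and Doc were 2.68-fold and 3.76-fold lower (log2 fold changes -1.43 and -1.91) and blood 8.88-fold lower.

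A general rise of all such transcripts would leave almost no family lower, but 30.2% of the families past the threshold fell. Reads moving between near-identical insertions would leave the family sum in place, and the sum of copia rose by 6.425 on the log2 scale. Different insertions in the stocks crossed for the genotypes may account for part of the rise, and for copia, at 78.8-fold, this cannot be told apart from an effect of the RNAi because genomic copy number is not analysed here. An effect of the genotype itself also stays open and was not tested.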

How the results depend on the processing

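Added after seeing the data were the fits with insertions, with protein-coding genes alone and without both control replicate 2 and ecd-RNAi replicate 1; the other settings were chosen before the data were examined. Genes higher, genes lower, ecd, Xrp1 and the number of lists past camera kept their direction and side of the threshold, or stayed within 1.5 times, in 99 comparisons with another setting. The 3 exceptions were the 2-fold threshold, which by construction left 816 genes higher and 424 lower, and the estimated correlation, which left 0 of 16 lists (2 at an unadjusted camera p under 0.05). Leaving out 1 library at a time gave 2621 to 2800 genes higher, 2723 to 2862 lower, 14 to 16 lists, ecd at 0.347 to 0.439 and Xrp1 at 1.567 to 1.728 on the log2 scale. Without both control replicate 2 and ecd-RNAi replicate 1, 2518 genes were higher and 2689 lower, 2458 and 2632 of them shared with the fit of all libraries. The authors' deposited table called 2948 genes higher and 2858 lower, of which 2638 and 2778 were shared and 0 went the opposite way. No named gene and none of the 16 called lists reversed, and reversals among the other called genes were counted only against the authors' deposited table. Of the named genes and lists, 11 gene and 36 list results lost their call: Fbp1 in 10 settings (adjusted p 0.0512 to 0.146), SmD3 in the authors' deposited table, the apoptosis list in 11, the ecdysone list in 10, the cell cycle list with quantile normalization, and all 16 lists with an estimated correlation. The cause was not tested. In the glutathione, autophagy and apoptosis lists the estimated correlation was close to the preset or below it, so a higher correlation does not account for that loss. After recentring on the median the median log2 fold change of antioxidant, heat shock, ribosome biogenesis, tRNA synthetase and neuronal lists turned negative (-0.03, -0.05, -0.07, -0.08 and -0.08). With quantile normalization that of the serine and one-carbon list went from -0.06 to 0.05 and that of the neuronal list from 0.01 to -0.26.

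The replicate numbers of the titles did not pair the libraries: deviations of same-numbered libraries correlated at 0.053, -0.052, -0.04 and -0.017. The deposited column names number the libraries otherwise, and would match control replicates 1, 2 and 3 with ecd-RNAi replicates 2, 3 and 4. Those pairs correlated at -0.012, -0.027 and 0.007. The replicate block used the numbers of the titles. With the replicate block 2796 genes were higher and 2883 lower and 14 lists passed, with ecd at 0.39 and Xrp1 at 1.64. The planned edgeR and DESeq2 tests on recovered reads were not run, because whole reads could not be recovered. Depth limits calls near the floor of 3 reads per library: 28 tested genes were at 0 in all controls and 10 in all libraries labelled ecd-RNAi.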

Other observations

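The tests of ecd were chosen only after the result was seen; the tests of other groupings of the libraries and of intron content were fixed before the data were examined. The genes in the next 2 paragraphs were chosen after their values were seen, and all adjusted p are from limma with Benjamini-Hochberg adjustment.

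The libraries labelled ecd-RNAi held more chinmo, a factor that marks early larval stages (10830 ± 1264 against 711 ± 183 normalized counts, SD, n = 4, 15.2-fold, adjusted p = 1.94e-08). They held less of the let-7 complex precursor lncRNA:let7C (159 ± 80.7 against 2288 ± 210, 14.4-fold lower, adjusted p = 7.25e-06) and of br, an ecdysone target that promotes metamorphosis (14870 ± 1870 against 49910 ± 5327, 3.36-fold lower, adjusted p = 2.08e-07). The sex determination gene dsx was 2.00-fold lower (1528 ± 75.5 against 3063 ± 95.6, adjusted p = 3.19e-08). All 4 libraries of each group lay apart for these genes. Whether the groups had reached the same developmental stage on the day of dissection was not tested, and stage cannot be told apart from genotype here.

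Arc1, a capsid gene derived from a retrotransposon, rose from 1541 ± 1157 to 373100 ± 80950 normalized counts (242-fold, and 384-fold without control replicate 2), and its neighbour Arc2 rose 24.3-fold. The sugar receptor genes Gr64a to Gr64e, a cluster on chromosome 3L between 4026769 and 4035703, were at 0 in all controls and averaged 146 to 307 normalized counts, at least 42.8-fold higher, although several share exons and are not independent. In the Toll pathway, whose factor Dif was among the named genes, the ligand gene spz rose 10.96-fold and the protease gene psh 47.6-fold. The sodium channel gene ppk13 rose at least 307-fold and the dopamine receptor gene Dop2R 198-fold. The Y-linked gene WDY rose 16.5-fold from 133 ± 10.1 to 2197 ± 591, while roX1 and roX2, the RNAs of male dosage compensation, rose 1.49-fold and 1.41-fold and the female switch gene Sxl was 1.48-fold lower. The snRNA:U2:34ABa gene, one of several near-identical U2 copies whose reads may be shared, rose 207-fold.

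Of 35 splits of the 8 libraries into 4 and 4, the real one alone (1 split) gave 5859 genes past the limma threshold. The highest of the others gave 0, or 539 at an unadjusted p under 0.05. The other splits mix the 2 groups, which widens the spread within each set of 4, so few calls were likely in them beforehand. A share of 1 in 35 is the smallest that these splits can give. They also cannot tell the RNAi from any other difference between the groups.

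The targeted gene ecd was higher in the libraries labelled ecd-RNAi. With the same mix of cells in both groups, cells outside the nubbin domain would dilute a fall but could not turn it into a rise. The log2 fold change less 2 standard errors was 0.269. Whether the mix of cells differed between the groups was not tested. The rise also held under other scalings: the lowest such value under quantile normalization and recentring was 0.179. Both start from the authors' values and assume that the libraries share a distribution or a median, while 62.5% of genes passed. A scaling error that survives this assumption is therefore not excluded. Reads of the RNAi hairpin counted as ecd may explain the log2 fold change of 0.387, and cannot be told apart from the endogenous transcript because only 1 value per gene was used. Compensation by the gene itself also stays open: the ratio of the group means was 1.312. An exchange of the labels of the whole groups would put the rises of Xrp1 (3.09-fold) and Ilp8 (180.0-fold) in discs without the RNAi construct. The same would hold for the stress genes of the JNK list, of which 21 of 28 rose and 4 fell. This argues against an exchange, but no value used here is tied to the genotype, so an exchange is not excluded. The wing pouch list was lower (29 of 38, median -0.41), but so was the notum and hinge list (15 of 18, median -0.49). The fall was thus not particular to the pouch list. The notum and hinge list mixes genes of both regions, and part of the hinge lies in the driver's domain. It therefore cannot show whether the fall followed that domain, and the fall does not speak for or against the labels.

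A hypothesis from the role of ecd in splicing was that genes with introns in every isoform lose transcript relative to intronless genes. The median log2 fold change was -0.01 over 7678 genes with introns in every isoform and 0.04 over 773 intronless genes. Matched on mean expression in 10 bins, the difference of medians was 0.006 (bootstrap 95% interval over genes -0.036 to 0.099, 1000 draws, genes not being independent replicates). This argues against a fall of 0.1 between these classes in whole discs, a cut-off set in advance. A smaller fall, or one diluted by cells outside the driver's domain, is not excluded. By intron number, looked at after the values were seen and not matched on expression, 136 of 585 genes with over 10 introns rose and 278 fell (median -0.14, unadjusted camera p = 0.00379, or p = 0.426 with an estimated correlation). The medians were 0.035, 0.032 and 0.038 with 0, 1 and 2 to 3 introns, -0.025 with 4 to 6 and -0.077 with 7 to 10. In these other classes the unadjusted camera p lay between 0.0716 and 0.73.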
